A study of Homo sapiens with 2 samples.

How the data were processed

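Whole-genome bisulfite sequencing was carried out on genomic DNA of 2 cultured, untreated breast cancer cell lines, named 468LN (labelled a metastasis) and 468PT (labelled a cancer), with 1 library per line. Bisulfite treatment converts unmethylated cytosine to uracil, which is read as thymine, whereas methylated cytosine is still read as cytosine. Per the labels' protocols, DNA was sheared by sonication, ligated to methylated adaptors, converted with a bisulfite kit, size-selected on a gel, amplified by PCR and sequenced as paired-end reads on an Illumina instrument. The labels' protocols name SOAPaligner2 as the aligner, whereas the submitters' processing notes list Bowtie 0.12.8, Bismark and the hg19 genome build. Which of these aligners made the values is not given in the sources used here, nor are read filters or the treatment of PCR duplicates.

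The authors deposited, for each library, the count of methylated and the count of unmethylated reads at each of 28217448 CpGs, as raw counts with no normalization. Each CpG had 1 line, since no 2 positions on a chromosome lay closer than 2 bp. Whether reads of both strands were summed is not given in the sources used here. The deposited tables carry no header. The first of the 2 count columns was taken as methylated, because it held under 0.1% of the reads at mitochondrial CpGs in both libraries and because CpG-dense runs with at least 100 tested CpGs had medians of 11.5% in 468LN and 1.87% in 468PT on that reading. Positions are those in the tables on hg19.

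Chromosomes 1 to 22 and X were analysed, which left 27999103 CpGs. The Y chromosome was left out, and mitochondrial CpGs served only as a measure of incomplete conversion. Intervals of methylation levels are Wilson 95% intervals on read counts and cover counting error only, as PCR copies are not independent molecules. Intervals of shares of dense runs or of CpGs are Wilson 95% intervals on the numbers of runs or CpGs, which are not independent, and that of a ratio of CpG numbers is a 95% interval on the log scale. With 1 library per line there was no replicate check. Every test therefore compares these 2 libraries and not the lines, and differences are given as 468LN minus 468PT in percentage points. Rise, fall, loss and gain describe 468LN relative to 468PT and imply no order of descent.

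CpGs with at least 5 reads in both libraries were tested with a two-sided Fisher's exact test on methylated and unmethylated reads. The same test was applied to summed reads of non-overlapping 1-kb tiles and of CpG-dense runs, each with at least 5 such CpGs. A run held at least 20 CpGs with gaps of at most 50 bp. Runs stood in for CpG islands, since island calling from sequence needs an hg19 genome, which was not used here. Adjustment was by the Benjamini-Hochberg method within each kind of feature. A feature was called at an adjusted p under 0.05 together with a difference of at least 25 points. Reads that span several CpGs are not independent, so p-values of tiles and runs are too small and the size threshold carries most of the call. A quasi-binomial test with the spread between CpGs as overdispersion was run as an alternative. Bins of 100 kb with at least 100 tested CpGs were described without a test.

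The test functions were tested on simulated data with the real positions and depths and 200 changed features. All CpGs of a changed feature were set to the middle of the scale, and the libraries were moved apart equally from there. Real changes often start near an end of the scale and vary between CpGs, which the simulation leaves out. Of 1748836 simulated tiles, 91% of those changed by 30 points and 100% of those changed by 50 points were recovered, with 503 and 496 unchanged tiles called. Unchanged tiles called thus outnumbered the changed tiles recovered (182 and 200). Of 70515 simulated dense runs, the recovered shares were 99% and 100%, with 4 and 3 unchanged runs called. Of 344525 simulated CpGs of chromosome 21, 61% of those changed by 50 points and 94.5% of those changed by 80 points were recovered. The median depth of that chromosome was 38 reads in 468LN and 50 in 468PT. Simulated reads were drawn independently at each CpG, so the numbers of unchanged features called leave out the dependence of reads that span several CpGs.

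Named regions followed a rule set before the data were examined, as were Fisher's exact test of CpGs, tiles and dense runs and the thresholds of its calls (the closing section names the tests of explanations that were chosen later): the 3 bins of 100 kb with the largest rise and the 3 with the largest fall, and the 3 longest stretches of adjacent called tiles in each direction. The rule's parts on promoters, the gene list comparisons and the promoter test were planned but not run, because they need an annotation of hg19, which was not used here. The 3 dense runs per direction with at least 100 tested CpGs and the largest difference were named by a rule set after the data were seen. Alternatives covered the coverage minimum, the size threshold, the number of CpGs per region, thinning of the deeper library, autosomes alone, removal of CpGs above 3 times the median depth, unweighted means and the quasi-binomial test. Alternatives chosen after seeing the data were restriction to 1-Mb windows of equal relative depth (log2 ratio within 0.25 of 0) and subtraction of the median tile difference of -8.82 points. Relative depth is the median depth of a 1-Mb window, or the mean depth of a named region or 10-kb window, over the library median. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0.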

Results

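DNA methylation was measured at base resolution in 468LN and 468PT, cultured breast cancer cells whose names match derivatives of the MDA-MB-468 carcinoma line. The labels give no parental line and mark 468LN as a metastasis and 468PT as a cancer. Each line was represented by 1 library, so no value below has a replicate error. Chromosomes 1 to 22 and X received 1024022995 CpG calls in 468LN and 1030500280 in 468PT. The median depth per CpG was 29 reads in 468LN and 30 reads in 468PT. Depth was less even in 468LN, with 10th and 90th percentiles of 4 and 73 reads against 8 and 65 reads in 468PT. At least 5 reads were present at 89.4% of CpGs in 468LN and 94% in 468PT. At mitochondrial CpGs, which are taken to be unmethylated, 0.0687% of calls were methylated in 468LN (95% interval 0.068 to 0.0694) and 0.0635% in 468PT (0.0624 to 0.0646), so incomplete conversion was low in both libraries.

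The series set the methylome of a metastatic breast cancer type against that of a primary one. The 468LN genome was less methylated than the 468PT genome. Over all CpGs, 45.3% of reads were methylated in 468LN (Wilson 95% interval 45.34 to 45.35) and 58.3% in 468PT (58.29 to 58.30), a difference of -12.9 points. The mean over the 24661120 CpGs with at least 5 reads in both was 45.6% in 468LN and 59% in 468PT. The median CpG stood at 42.9% in 468LN and at 80% in 468PT. The mean was lower in 468LN on 23 of 23 chromosomes, with differences from -8.64 points on chromosome 8 (41.8% in 468LN, 50.4% in 468PT) to -16.1 points on the X chromosome (39% in 468LN, 55% in 468PT). These differences far exceed the counting error, but the spread between cultures of a line was not measured.

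**Figure D1:**
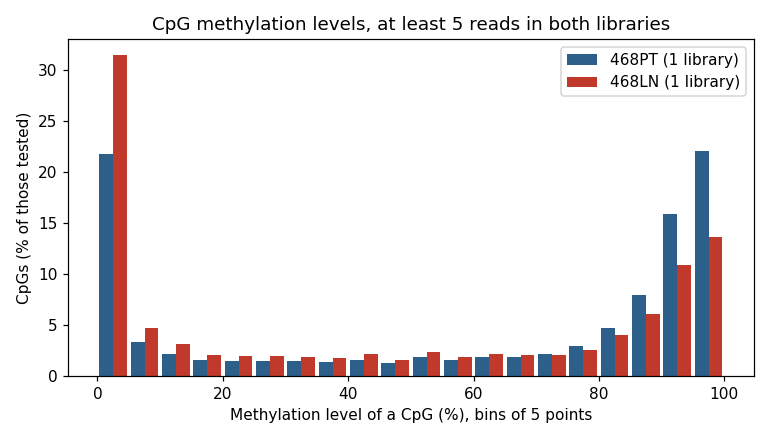
Share of the 24661120 tested CpGs (y axis, %) at each methylation level (x axis, bins of 5 points) in the 468PT library (blue) and the 468LN library (red). The low end holds more CpGs in 468LN and the high end more in 468PT, with 34% of CpGs over 80% methylated in 468LN against 49.9% in 468PT.

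Most CpGs were near one end of the scale in both libraries. In 468LN, 41.3% of tested CpGs were under 20% methylated, 24.8% were between 20% and 80%, and 34% were over 80%. In 468PT the shares were 28.8%, 21.3% and 49.9%. Of the 12317975 CpGs over 80% in 468PT, 55.5% were also over 80% in 468LN, 26.8% were intermediate and 17.7% were under 20%. Of the 7095495 CpGs under 20% in 468PT, 76.4% were also under 20% and 8.21% were over 80% in 468LN. By Fisher's exact test with Benjamini-Hochberg adjustment, 6350524 CpGs (25.8%) were called lower and 1898965 (7.7%) higher in 468LN.

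The lower level of 468LN was also seen in regions. Of 1748836 tiles of 1 kb, with a median of 10 CpGs and of 319 reads in 468LN and 334 in 468PT, 551888 (31.6%) were called lower and 119362 (6.83%) higher in 468LN. The median tile difference was -8.82 points, with quartiles of -33.4 and 0. Of 254414 stretches of adjacent tiles called lower, 149644 were a single tile. Stretches of at least 10 adjacent tiles called lower numbered 5527 and held 15.6% of the tiles called lower, against 509 stretches and 5.98% of the tiles called higher. Tiles called lower were 4.62 times as many, which by itself lengthens stretches. The quasi-binomial test, which allows for spread between CpGs, called 460166 tiles lower and 95031 higher.

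The longest stretches of tiles called lower lay on chromosomes 11 and 4. The stretch from 70415001 to 70532000 on chromosome 11 (117 kb, 2393 CpGs) was 11.7% methylated in 468LN (95% interval 11.5 to 11.9) and 87.7% in 468PT (87.5 to 87.8). A second stretch on chromosome 11, from 70705001 to 70814000 (109 kb), was at 8.22% in 468LN and 90% in 468PT. The stretch from 7434001 to 7546000 on chromosome 4 (112 kb) was at 5.55% in 468LN and 79% in 468PT. The longest stretches of tiles called higher were shorter. On chromosome 22, the stretch from 34082001 to 34155000 (73 kb) was at 85.6% in 468LN and 10.3% in 468PT, and that from 33776001 to 33817000 (41 kb) was at 88.8% and 9.84%. On chromosome 6, the stretch from 166216001 to 166258000 (42 kb) was at 89.3% in 468LN and 16.1% in 468PT. All coordinates are on hg19, and genes in these intervals were not analysed here.

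At the scale of 100 kb, the 2 libraries differed in which domains were methylated. Over 28380 bins the median difference was -9.47 points, with quartiles of -26 and -2.16. Bins at least 20 points lower in 468LN made up 31.1%, and bins at least 20 points higher made up 6.84%. Lower bins outnumbered higher bins on 23 of 23 chromosomes. Bins over 70% methylated made up 41.5% in 468PT and 14.7% in 468LN, and bins under 30% made up 28.9% and 40.9%. Of the 11790 bins over 70% in 468PT, 3500 (29.7%) were over 70%, 5696 (48.3%) were intermediate and 2594 (22%) were under 30% in 468LN. Of the 8196 bins under 30% in 468PT, 6184 (75.5%) were also under 30% in 468LN, and 340 (4.15%) were over 70%. Across bins, which are not independent, methylation in one library was related to that in the other with a Pearson r of 0.559 and a Spearman rho of 0.56.

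**Figure D2:**
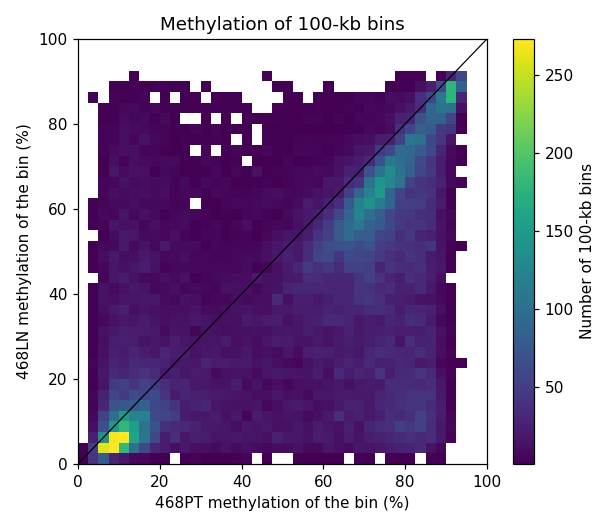
Methylation of 28380 bins of 100 kb in 468PT (x axis, %) against 468LN (y axis, %), coloured by the number of bins, with the line of equality in black. Most bins lie below the line, and a faint spread at the lower right holds the 2594 bins over 70% in 468PT and under 30% in 468LN.

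Low-methylation domains covered more of the genome in 468LN, in shorter pieces. Bins under 30% summed to 1160.1 Mb in 468LN, in 2431 contiguous domains, and to 819.6 Mb in 468PT, in 1071 domains. Domains of at least 1 Mb, however, held 516.4 Mb in 468LN and 520.9 Mb in 468PT. The longest such domain of 468LN spanned 4.7 Mb on chromosome 5 (21700001 to 26400000), at 10.2% in 468LN and 32.3% in 468PT. That of 468PT spanned 7.2 Mb on chromosome 21 (19700001 to 26900000), at 14.5% in 468PT and 13.1% in 468LN.

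In the bins with the largest differences, 1 library was almost unmethylated and the other highly methylated. The bin from 209500001 to 209600000 on chromosome 2 was at 2.1% in 468LN (95% interval 1.86 to 2.38) and 89.2% in 468PT (88.6 to 89.7). The bin from 50900001 to 51000000 on chromosome 2 was at 3.06% in 468LN and 88.3% in 468PT, and that from 108900001 to 109000000 on chromosome 1 was at 4.71% and 89.7%. In the other direction, adjacent bins on chromosome 5, from 158200001 to 158300000 and from 158300001 to 158400000, were at 86.8% and 84.1% in 468LN and at 4.21% and 6.44% in 468PT. A further bin on chromosome 5, from 8600001 to 8700000, was at 89.1% in 468LN (88.7 to 89.5) and 8.97% in 468PT (8.68 to 9.27). The relative depth of these 6 bins was between 0.788 and 1.47 in 468LN and between 1.07 and 2.12 in 468PT.

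**Figure D3:**
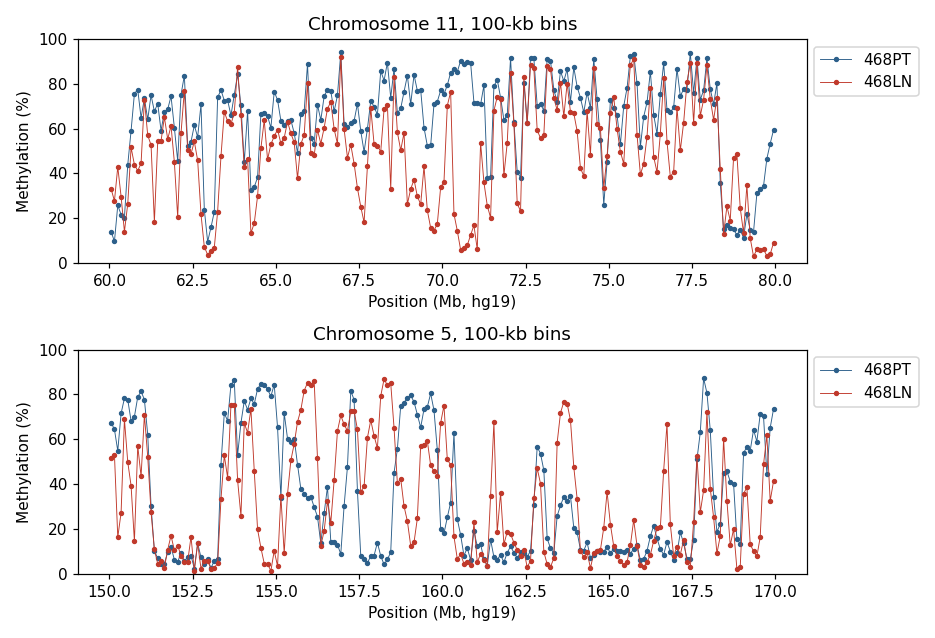
Methylation of 100-kb bins (y axis, %) along 60 to 80 Mb of chromosome 11 and 150 to 170 Mb of chromosome 5 (x axis, hg19) in 468PT (blue) and 468LN (red). The low part of the red line near the middle of the chromosome 11 plot holds the stretch from 70415001 to 70532000 (11.7% in 468LN, 87.7% in 468PT), and its peak on chromosome 5 holds the bin from 158200001 to 158300000 (86.8% in 468LN, 4.21% in 468PT).

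In CpG-dense sequence, which includes CpG islands, the median over runs and the mean over CpGs differed in sign. The median dense run was at 54.8% in 468LN and 65.6% in 468PT, with a median difference per run of -2.13 points and quartiles of -16.7 and 1.15. Inside dense runs (3139114 tested CpGs) the mean was 42.9% in 468LN and 41.6% in 468PT, a difference of 1.28 points that was negative on 4 of 23 chromosomes. Within 2 kb of a run the mean was 50.6% in 468LN and 64.1% in 468PT, and between 2 and 4 kb it was 53.2% and 69.4%. Beyond 4 kb it was 44.5% in 468LN and 60.3% in 468PT. In each of the 3 outer classes the mean was lower in 468LN on 23 of 23 chromosomes. Inside runs, 14% of CpGs were called higher and 12.3% lower, against 6.97% higher and 28.1% lower beyond 4 kb.

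Among 70515 dense runs tested as units by Fisher's exact test, 11948 (16.9%) were called lower and 7106 (10.1%) higher in 468LN, so that 62.7% of calls were lower. Once the median tile difference was subtracted, 45.3% of calls were lower (7664 lower, 9236 higher), so which direction prevails among all runs depended on this choice. The value subtracted was the median of tiles (-8.82 points) and not the smaller one of runs (-2.13 points), which favours higher calls among runs. The directions differed between runs of different size, which also differed in 468PT level (next paragraph). Of 33193 runs with 20 to 29 tested CpGs, 22.2% were called lower and 6.68% higher. Of 14257 runs with 30 to 49 CpGs, 16.3% were lower and 9.83% higher, a split that turned to 1427 lower and 1828 higher after the subtraction. Of 11771 runs with 50 to 99 CpGs, 7.28% were lower and 15.5% higher. Of 6426 runs with at least 100 CpGs, 145 (2.26%) were lower and 1391 (21.6%) higher, with more higher than lower on 23 of 23 chromosomes.

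**Figure D4:**
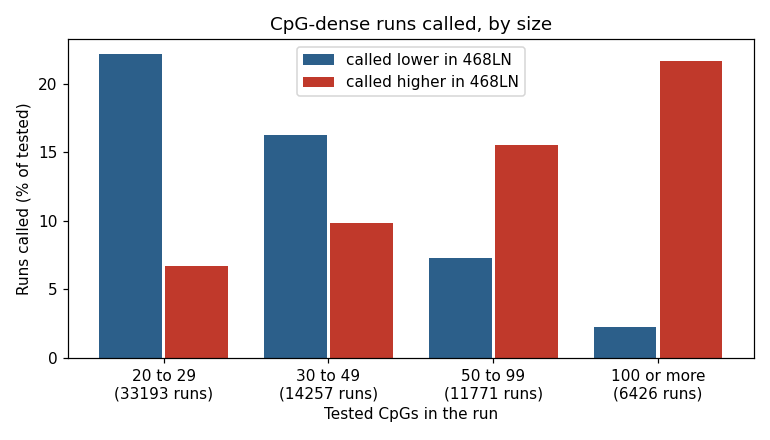
Percentage of tested CpG-dense runs (y axis) called lower (blue) or higher (red) in 468LN, by the number of tested CpGs in the run (x axis). Lower calls fall from 22.2% to 2.26% and higher calls rise from 6.68% to 21.6% from the smallest to the largest class shown. The 468PT level also differed between the classes.

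The 468PT level differed between these size classes, so the split by size cannot be credited to size alone. A run over 80% in 468PT cannot be called higher at a threshold of 25 points, and one under 20% cannot be called lower. The median 468PT level was 81% for runs with 20 to 29 CpGs and 1.87% for runs with at least 100 CpGs. Among runs under 20% in 468PT, the share called higher was 24.5% for 20 to 29 CpGs and 21.1% for at least 100 CpGs. Among runs over 80% in 468PT, the share called lower was 25.4% for 20 to 29 CpGs and 9.94% for at least 100 CpGs. Within these levels, larger runs were thus not more often called higher, but were less often called lower. Of all 19588 runs under 20% in 468PT, 14391 were also under 20% in 468LN, 4128 were intermediate and 1069 were over 80%. Of 28228 runs over 80% in 468PT, 732 were under 20% and 15410 over 80% in 468LN.

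The largest rises among runs of at least 100 CpGs were at runs almost unmethylated in 468PT and almost fully methylated in 468LN. The run from 158449661 to 158450597 on chromosome 3 (104 CpGs) was at 94.2% in 468LN (95% interval 93.7 to 94.7) and 0.529% in 468PT (0.364 to 0.769). The run from 54966653 to 54967715 on chromosome 16 was at 93.6% in 468LN and 0.434% in 468PT, and that from 36771715 to 36772787 on chromosome 1 was at 93.6% and 0.817%. The largest falls were on the X chromosome, from 9732679 to 9734064 (0.502% in 468LN, 89.1% in 468PT), on chromosome 5, from 83430 to 85647 (1.47% and 87.8%), and on chromosome 1, from 6268402 to 6269636 (9.94% and 93%). Depth was uneven at each of these falls. The relative depth was 1.36 in 468LN and 0.492 in 468PT at the X run, and 0.513 and 1.14 at the chromosome 5 run. At the chromosome 1 run that fell it was 2.19 and 0.534. Among the runs with the largest rises it was between 1.4 and 2.72 in 468LN and between 1.64 and 2.47 in 468PT. These 6 runs were chosen after the values were seen.

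Dense runs were also grouped by the change of their surroundings, taken as the CpGs outside dense runs in the same 100-kb bin. In bins that rose by at least 20 points, 967 of 2399 runs (40.3%) were called higher and 181 (7.54%) lower. In bins that moved by under 20 points, 3527 of 45786 runs (7.7%) were higher and 3609 (7.88%) lower. In bins that fell by at least 20 points, 8146 of 22216 runs (36.7%) were lower, and 2603 (11.7%) were higher. Among runs under 20% in 468PT, 39.3% of 5466 were called higher in bins that fell, 15.3% of 13874 in bins that moved by under 20 points and 43.4% of 221 in bins that rose. The share in bins that fell exceeded that in bins that moved by under 20 points on 23 of 23 chromosomes, and its interval (38 to 40.6) overlapped that in bins that rose (37.1 to 50). Among runs at 20% to 80% in 468PT, 7.65% of 5946 were called higher in bins that fell, 9.59% of 14634 in bins that moved by under 20 points and 42.1% of 2069 in bins that rose.

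Read depth along the genome differed between the libraries. Over 2873 windows of 1 Mb, relative depth in 468LN and 468PT was related with a Spearman rho of 0.413, and only 883 windows (30.7%) had a log2 ratio within 0.25 of 0. From 54000001 to 58000000 on chromosome 7, the median relative depth was 10.2 in 468PT and 0.776 in 468LN. It peaked at 29.1 in 468PT between 55000001 and 56000000, where 468LN stood at 1. CpGs of this block averaged 26.8% methylation in 468LN and 47.7% in 468PT. In windows of equal relative depth, the genome-wide difference was -12.9 points. Of 20700 isolated CpGs at 10% or less in 468PT inside tiles methylated in both libraries, 34.9% were at 90% or more in 468LN and 28.8% were also low there. Of 19772 such CpGs at 10% or less in 468LN, 29.8% were at 90% or more in 468PT and 30.2% were also low there. The closing section weighs these CpGs against descent of both lines from 1 donor.

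**Figure D5:**
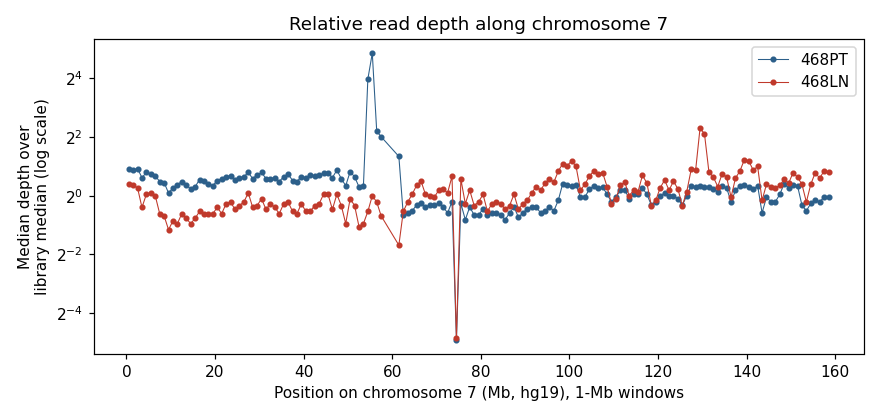
Median read depth of 1-Mb windows over the library median (y axis, log scale) along chromosome 7 (x axis, Mb, hg19) in 468PT (blue) and 468LN (red). 468PT peaks at 29.1 between 55 and 56 Mb, where 468LN is at 1, and 468LN has a peak of its own from 129000001 to 131000000 with a median of 4.64.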

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

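The tests of conversion, the donor comparison in stricter tiles, the separate tests of isolated CpGs in 468PT and in stricter tiles, the test of runs in bins that fell and the tests at equal 468PT level were chosen after the results were seen; the other tests below were set before.

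Relative read depth, which is not a methylation measurement, stood out in several blocks at 3 or more times the library median. In 468PT the median relative depth was 10.2 on chromosome 7 (54000001 to 58000000), 4.07 on chromosome 19 (10000001 to 11000000), 4.69 on chromosome 21 (10000001 to 12000000), and 3.2 and 3.1 on chromosome 9 (35000001 to 36000000 and 37000001 to 38000000). In 468LN it was 4.64 on chromosome 7 (129000001 to 131000000), 6.17 on chromosome 10 (39000001 to 40000000) and 3 on chromosome 16 (34000001 to 35000000). In the same blocks the other library stood between 0.776 and 2.53. Depth in 468LN also followed the number of CpGs per window more closely (Spearman rho 0.617 across windows, against 0.316 in 468PT).

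Isolated CpGs were read as unmethylated inside tiles that were otherwise methylated in both libraries, in data that no test of tiles or runs singled out. Among 2612872 CpGs with at least 15 reads in both libraries, in tiles whose other CpGs were at 85% or more, 19772 were at 10% or less in 468LN. Of these, 29.8% were at 90% or more in 468PT and 30.2% were also low in 468PT. Conversely, 20700 were at 10% or less in 468PT. Of these, 34.9% were at 90% or more in 468LN and 28.8% were also low in 468LN. A C-to-T base difference at a CpG is read as an unmethylated cytosine in bisulfite data.

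In windows where the other library kept intermediate isolated CpGs, 29.7% of the low CpGs of 468LN and 35% of those of 468PT were methylated in the other library, above the bound of 10% set for descent from 1 donor with acquired changes, although that filter was weak because intermediate levels also arise without a base difference. In stricter tiles and windows, 120 of 489 CpGs of 468LN (24.5%, 95% interval 20.9 to 28.5) and 871 of 2264 of 468PT (38.5%, 36.5 to 40.5) were still methylated in the other library, against 127 (26%) and 537 (23.7%) that were low in both, and the shares still methylated are consistent with cells of different donors. Loss of methylation at single CpGs without a base change would spread over low levels, but in 468PT CpGs at 0 to 5% were 13 times as many as those at 10 to 15%. In 468LN the ratio was 3.47, which leaves it open. In stricter tiles the 468LN ratio was 5.65 (95% interval 5.12 to 6.23), against a bound of 5. These ratios counted all isolated CpGs of a level, among them CpGs low in both libraries. The stricter 468LN ratio therefore does not decide whether the 468LN CpGs that were methylated in 468PT had a base change. As a hypothesis, 1 of the 2 cultures may be mislabelled or cross-contaminated, which a comparison with reference genotype profiles would decide and which was not tested here. MDA-MB-468 is known for an amplified EGFR gene on the short arm of chromosome 7, and the deep block on that chromosome appeared in 468PT and not in 468LN, but whether it holds the gene was not checked.

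CpGs in tiles methylated in both libraries made up 1.92% of the CpGs called lower and 2.17% of those called higher. The comparison of isolated CpGs covered only 2612872 of the 24661120 tested CpGs. Base differences at the other CpGs were not counted. These shares therefore do not measure how many calls of single CpGs reflect a base difference.

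The lower methylation of 468LN was weighed against conversion, depth and chromosome segments. The methylated share at mitochondrial CpGs differed by 0.00519 points between the libraries, and incomplete conversion in 468PT would need several points. Excess conversion of methylated cytosines in 468LN would lower the most methylated bins as much as the genome. The 95th percentile of bins was 82.5% in 468LN against 88.5% in 468PT, a smaller gap than the genome-wide one. Excess conversion also cannot raise bins, and some rose by up to 82.6 points. These values argue against it as the whole cause of the difference. A partial contribution is left open, because CpGs taken to be unmethylated, such as mitochondrial ones, cannot show excess conversion. At CpGs with 20 to 40 reads in both libraries and the deeper at most 25% above the shallower the difference was -13 points, which argues against depth as the cause. In windows of equal relative depth the mean difference was -12.2 points. This argues against copy number changes that show as unequal relative depth as the cause. Changes that leave relative depth equal, such as loss of 1 allele with gain of the other, were not tested. The difference between metastasis and cancer that the labels name stays open and untested, since line, donor, culture and library cannot be separated with 1 library each.

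The rise of CpG-dense runs in 468LN was weighed against their surroundings and depth. The share of runs called higher was 3.44 times as large in bins that rose as in bins that fell, but this depended on the level in 468PT. Among runs at 20% to 80% in 468PT the ratio was 5.5 (42.1% against 7.65%), although most runs called higher lay in other bins, with 871 in bins that rose, 1404 in bins that moved by under 20 points (9.59%) and 455 in bins that fell. Among runs under 20% in 468PT it was 1.11 (43.4% of 221 runs, 95% interval 37.1 to 50, against 39.3% of 5466, 38 to 40.6), which does not separate bins that rose from bins that fell, and the share in bins that fell was 2.57 times that in bins that moved by under 20 points (15.3%), so higher calls of these runs were more frequent where the surroundings moved in either direction. Limiting runs to pairs of depths with the larger at most 25% above the smaller kept 21896 of 70515 runs. The share called higher was then 9.98%, 0.99 of its value among all runs (10.1%). This argues against unequal depth of a run between the libraries as the cause. A bias tied to CpG density was not tested.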

How the results depend on the processing

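The alternatives of equal relative depth and of the subtracted median were chosen after the results were seen. No paired analysis was possible because each line has 1 library, and no replicate could be left out. Promoter, gene list and named promoter alternatives were not run, as hg19 gene positions were not used here. Of 80 alternative values, 57 stayed close, 23 moved and 0 reversed. Each count was set against its own main value, so the tally cannot show a change in which direction prevailed. Among dense runs that direction did change after the subtraction given below. Counts of calls and shares of bins stayed close when within 1.5 times the main value, and differences in points when within the width of the counting interval of the genome-wide level, a far narrower margin. The genome-wide difference of -12.9 points was -13.4 as an unweighted mean, -13.1 with 10 reads or more, -12.91 on autosomes, -12.5 without CpGs above 3 times the median depth and -12.94 in windows of equal relative depth (chosen after seeing the data). The median 100-kb bin difference of -9.47 points was -8.9 unweighted, -8.48 in bins of 10 kb and -9.42 with 10 reads or more. With a minimum difference of 40 points, 359655 tiles were lower and 72220 higher, and 5497 dense runs were lower and 4498 higher. With 10 points, 836089 tiles were lower and 207303 higher, and 23371 runs were lower and 11197 higher. Requiring 10 CpGs per tile gave 259569 lower and 49528 higher, with fewer tiles tested (876338 against 1748836). Calls in both directions dropped by a larger factor than the tiles tested, so their number alone does not account for the drop. Windows of equal relative depth, also fewer, gave 164395 tiles lower and 41078 higher, and 3205 runs lower and 2254 higher. After subtraction of the median tile difference (chosen after seeing the data), 7664 runs were lower, under the 9236 higher. In each of the other alternatives for CpGs, tiles and runs, lower calls outnumbered higher calls. In the simulation, 61% of changes of 50 points were recovered at single CpGs of chromosome 21, against 100% at tiles and dense runs. Depth was not varied there. Only 200 features were changed, far fewer than were called in the data, so these shares are not those of the real calls.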

Other observations

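Windows of very high depth were also less methylated in 468LN. In 23 windows of 10 kb the mean depth was at least 20 times the library median in both libraries, and the methylation level was lower in 468LN in 23 of 23. On chromosome 16, the windows from 46380001 to 46390000 and from 46390001 to 46400000 were at 1.92% and 2.29% in 468LN and at 37.4% and 36.7% in 468PT. On chromosome 10, the window from 42380001 to 42390000 was at 3.46% in 468LN and 53.8% in 468PT, and that from 42390001 to 42400000 was at 5.89% and 62.4%. The window from 121480001 to 121490000 on chromosome 1 differed less, at 53.4% in 468LN and 64.7% in 468PT. The sequence content and copy number of these windows were not tested. These windows held 3.61% of calls in 468LN and 5.02% in 468PT.

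Mitochondrial CpGs took 5.29% of all CpG calls in 468LN (57428875 calls) and 1.98% in 468PT (20780905 calls). Of 439 mitochondrial CpGs listed, 354 had reads in each library.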
